A study of Arabidopsis thaliana with 2 samples.

How the data were processed

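Total RNA of Arabidopsis thaliana seedlings was measured on Affymetrix 3′ expression arrays, with 1 array for the C24 wild type and 1 array for the ros1-1 mutant. The genotype label of the mutant does not name its background. Per the labels' protocols, the seedlings grew for 15 days on MS medium at 22 °C under 16 h of light and 8 h of darkness, RNA was taken with a column kit, and biotin-labelled cRNA was hybridised. The deposited values are linear signal intensities per probe set, summarised by the authors with MAS5, per the submitters' processing notes. The software version, the scaling target and the detection calls are not given in the sources used here. The mean after trimming 2% of values from each end was 500.04 on both arrays, so the arrays carried a common scale as deposited. The genotype of each array was taken from its labels, and the array number limits the precision of every value.

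The table held 22810 probe sets, of which 64 control probe sets were set aside and 22746 were analysed. Names came from the array platform's annotation, updated through the TAIR10.1 gene table, which was used for names, gene types and the order of genes only. In this annotation 13513 probe sets had 1 gene, 503 had several and 8730 had none, and 13436 of the 13513 matched the gene table. No gene was named from a probe set with several genes.

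The ratio of each probe set was log2 of the ros1-1 signal minus log2 of the wild-type signal, with no further scaling. The floor was the 40th percentile of the values of both arrays, a signal of 132, and lower values were raised to it. A probe set counted as measured when its brighter array reached the floor. Where only 1 array reached it, the ratio is a bound. With 1 array per genotype there were no replicates, so no test was run and no p-value is given; differences were listed by a fixed rule of at least 2-fold. The scatter of probe sets of 1 gene about their mean, over genes with several probe sets above the floor on both arrays, was the estimate of measurement error. It leaves out differences between plants, extractions and labelling reactions.

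A gene's value was that of its brightest probe set. For each of 23 gene lists, the measured members and those at least 2-fold higher or lower were counted. For lists with at least 3 measured members, the median was placed among the medians of 10000 random lists matched on signal in 20 bins, as a description of these arrays. Genes in locus order were scanned in windows of 5 for at least 3 genes at least 2-fold higher, or at least 3 lower, and set beside 1000 random orders. Rules for chloroplast and mitochondrial locus codes, transposable elements and cytosolic ribosomal proteins took 0 probe sets, because the annotation used here does not carry those codes or words, and these lists are void. The lists for DNA methylation and RNA-directed silencing, flowering, seed storage, cell cycle, and phosphate and nitrate supply had 0 members with a named probe set and are void too. The ROS1 locus itself had no named probe set in the annotation used here and was not analysed here, so the mutated gene could not serve as a check on the array labels.

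Named genes were the 12 with the largest ratio in each direction among single-gene probe sets at or above the floor on both arrays, and the 5 with the largest bound in each direction among those measured on 1 array. Added to these were the list members at least 2-fold different, at most 4 a list, or otherwise up to 2 members given as values, and members of the DNA demethylation list at least 1.5-fold different, of which there were 0. Outside this rule, and chosen after their values were seen, are the further list members COR47, PYK10 and TIP41, the list members under the floor, AT3G16530, and the single chloroplast, defensin and CYP71B genes of the closing section. Probe sets ending in _s_at or _x_at can take signal from related genes. The size rule, the floor, the gene lists, the naming rule and the alternatives were fixed before the data were examined. A further 19 families drawn from gene symbols, gene types and chromosomes were added after the annotation was seen, and are described in the closing section only. In the defensin family, 2 peptide deformylases were removed after the values had been seen, and the chloroplast family was added then.

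The alternatives were a floor at the 25th or the 60th percentile, centring on the median, quantile normalization, removal of an intensity trend by lowess with a span of 0.3, an offset in place of the floor, thresholds of 1.5-fold and 3-fold, only probe sets ending in plain _at, the mean of a gene's probe sets, and windows of 10 genes. The steps were tested on simulated data, in which 200 of 22746 probe sets were changed in a simulated ros1-1 array against wild type with a scatter of 0.19 per log2 ratio. The 2-fold rule found 100% of the probe sets changed 3-fold or 4-fold, 40% of those changed exactly 2-fold and 0% of those changed 1.5-fold, and took 0 of 22546 unchanged ones. The changed probe sets were drawn from those at or above the 60th percentile of signal, and the same scatter was used at every signal. On the real arrays the SD of log2 ratios was 0.27, and 0.30 among the dimmer probe sets. These shares, and the absence of false calls, therefore do not carry over to the real arrays. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.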

Results

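Transcript levels were compared between 15-day seedlings of the Arabidopsis accession C24 and of the ros1-1 mutant, which carries a mutation in ROS1, a DNA glycosylase that removes methylated cytosines. The comparison asks which transcripts differ when this DNA demethylase is impaired. Each genotype was represented by 1 array and there were no replicates, so every difference below describes these 2 arrays. The median signal was 216 on the wild-type array and 213 on the ros1-1 array, and signals ran from 0.0647 to 20423 and from 0.0975 to 22469. In all, 14126 of 22746 probe sets reached the floor on at least 1 array, 13169 of them on both, and 8620 stayed under it on both. ROS1 itself was not analysed here, because no probe set carried its name in the annotation used.

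Most transcripts had similar signals on both arrays, and few named genes differed by 2-fold or more. Among named genes measured on both arrays, the largest difference was in PDF1.2, a plant defensin induced by jasmonate and ethylene, which was 4.32-fold lower in the ros1-1 array, with a signal of 3019 in wild type and 699 in the mutant. The related defensin PDF1.2b was 2.73-fold lower, at 10193 and 3740. The cold-regulated genes COR15A and COR15B, whose products protect chloroplast membranes during freezing, were 2.14-fold and 2.04-fold lower. The adjacent genes AT3G16670 and AT3G16660, which encode proteins of the pollen Ole e 1 family, were 2.96-fold and 2.78-fold higher in ros1-1.

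By the rule of size, 29 probe sets were at least 2-fold higher in ros1-1 and 34 were at least 2-fold lower, or 0.205% and 0.241% of those measured. Of these, 12 of the higher and 15 of the lower probe sets had 1 named gene, and 17 in each direction had none. At least 3-fold differences were found in 1 probe set higher and 10 lower. Across probe sets measured on both arrays, the log2 signals correlated with r = 0.982, a correlation across probe sets, which are not independent replicates. The SD of the log2 ratios was 0.27 and their median was -0.01. In 61 genes with several probe sets, a probe set's log2 ratio scattered about the mean of its gene with an SD of 0.19, against 1 for a 2-fold difference. This scatter was 0.22 in the dimmer part of the probe sets and 0.17 in the brighter part, divided at the median signal. The SD of all log2 ratios was 0.30 in the dimmer part, which held 35 of the 56 probe sets at least 2-fold different on both arrays. Differences between plants or RNA preparations of 1 genotype were not measured.

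**Figure D1:**
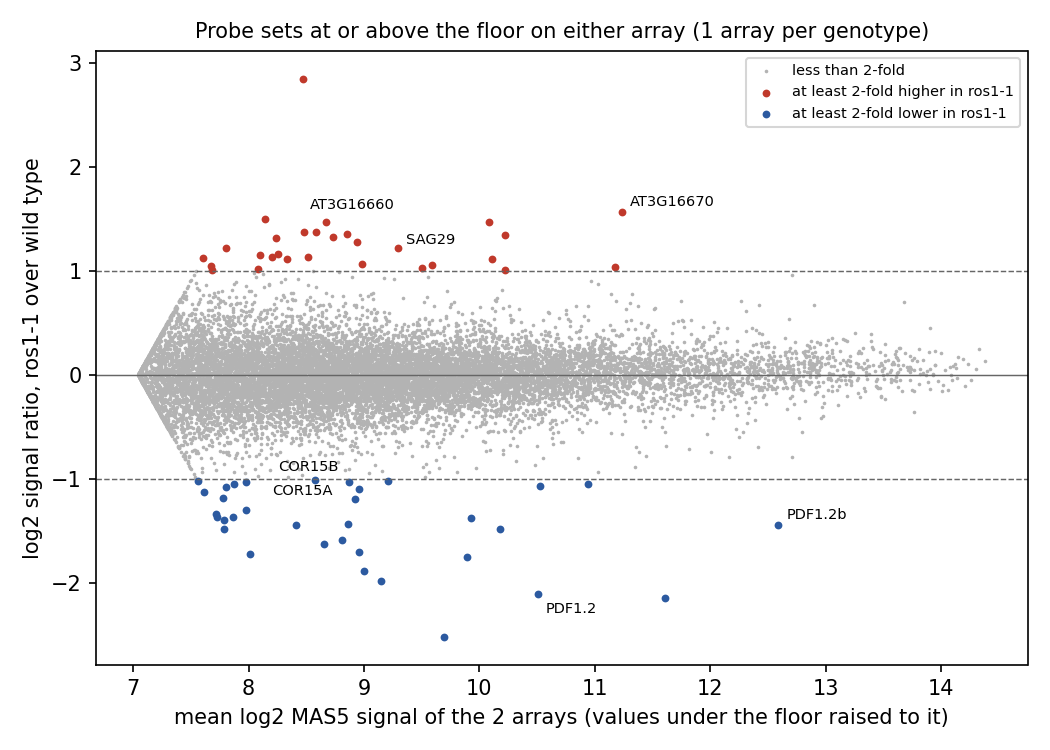
Log2 ratio of the MAS5 signals (ros1-1 over wild type, vertical axis) against the mean log2 signal of both arrays (horizontal axis), 1 point per probe set measured on at least 1 array. Dashed lines mark 2-fold; 29 probe sets lie on or above the upper line and 34 on or below the lower one, with PDF1.2 at -2.11 and AT3G16670 at 1.57.

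Among the other genes with higher signal in ros1-1, SAG29, also called SWEET15, a sucrose transporter of senescing tissue and seeds, had a signal of 411 in wild type and 957 in ros1-1, 2.33-fold higher. The sugar transporter-like gene AT3G05400 was 2.51-fold higher, and AT2G04050, of the MATE efflux family, was 2.58-fold higher. APL3, a large subunit of ADP-glucose pyrophosphorylase in starch synthesis, was 2.01-fold higher, from 145 to 292, close to the floor in wild type. AT4G36700, which encodes a cupin-domain protein, had signals of 652 and 1807 and was 2.77-fold higher. The remaining members of the 12 were AT3G15650 at 2.49-fold, AT1G80130 at 2.43-fold, AT1G10720 at 2.22-fold and AT1G43910, an AAA-type ATPase, at 2.16-fold higher, with AT2G41730 at a log2 ratio of 1.14. With the floor at the 60th percentile, log2 ratios were 0.93 for AT2G04050, 0.55 for AT3G15650 and 0.33 for AT1G10720. At that floor they were 0.43 for AT2G41730 and 0.54 for AT1G43910. The probe set of AT2G41730 can also take signal from related genes.

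Among the genes with lower signal in ros1-1, AT3G60520 went from 708 to 229, 3.10-fold lower. AT3G51670, a patellin with a lipid-binding SEC14 domain, was 2.80-fold lower, and AT2G36885 was 2.70-fold lower, at 764 and 283. ARLA1D, a small GTPase related to ADP-ribosylation factors, was 2.60-fold lower, and AT1G78450, a SOUL heme-binding protein gene, was 2.47-fold lower. AT3G11600 was 2.11-fold lower, the aspartyl protease gene AT1G09750 was 2.07-fold lower at 2835 and 1367, and AT2G21045, an arsenate reductase gene, was 2.04-fold lower. With the floor at the 60th percentile, the log2 ratios of AT1G78450 and AT2G21045 were -0.29 and -0.15. The probe set of PDF1.2b can take signal from related defensin genes, so its value is not of that gene alone.

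**Figure D2:**
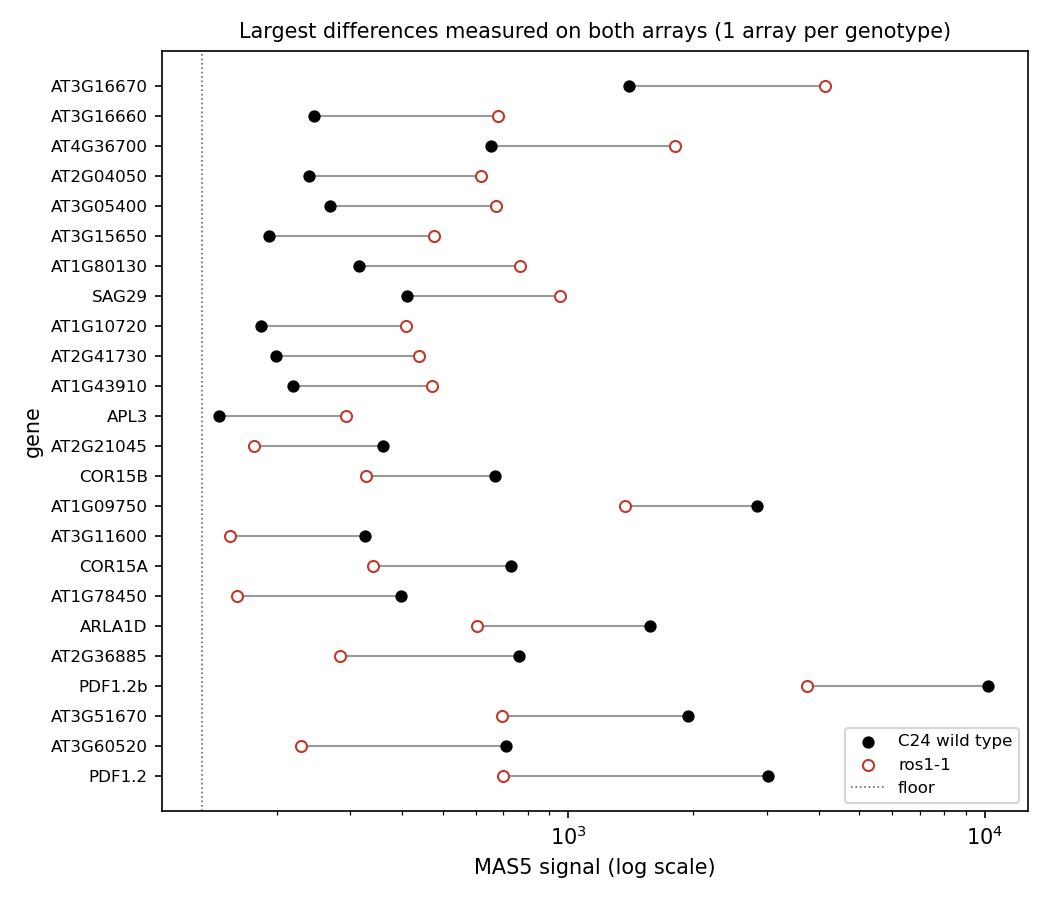
MAS5 signal on a log axis of the 12 genes with the largest ratio in each direction, with filled points for the C24 wild-type array, open points for the ros1-1 array and a dotted line at the floor of 132. Each point is 1 array; PDF1.2b had the highest wild-type signal of these genes, 10193.

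For genes measured on 1 array, only bounds were obtained. AT5G59330 had a signal of 334 in wild type and lay under the floor in ros1-1, at least 2.53-fold lower. Its log2 ratio was -0.04 with the floor at the 60th percentile and -0.95 with an offset in place of the floor. AT4G18650, a relative of the seed dormancy gene DOG1, had a signal of 289 in wild type against a deposited 30.0 in ros1-1, at least 2.19-fold lower. The ratio of its deposited values was 9.64-fold, and that of the extensin-like gene AT3G28550, at 57.2 in ros1-1, was 4.58-fold. With the floor at the 25th percentile their log2 ratios were -2.41 and -2.20, beyond that of PDF1.2. With an offset in place of the floor they were -1.38 and -1.06, against -1.92 for PDF1.2. Unspiked bacterial control probe sets, with signals up to 44.8, had log2 ratios from -2.87 to 3.58. Ratios over signals this far under the floor are uncertain, so these genes cannot be ranked against PDF1.2. The other lower bounds were 1.98-fold for AT3G28550, 1.88-fold for AT5G45480 and 1.86-fold for AT4G35905. In the higher direction, the bounds were just under 2.00-fold for AT1G19200, 1.95-fold for AT2G43620, a chitinase family gene, 1.87-fold for AT5G63130, 1.80-fold for the glutathione transferase gene GSTU25 and 1.79-fold for AT1G11850.

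Ratios larger than that of PDF1.2 were found in probe sets with no name in the annotation used here. Probe set 245275_at had a signal of 124 in wild type and 951 in ros1-1, at least 7.20-fold higher. Probe set 267461_at was 5.74-fold lower, from 1988 to 346, and 251109_at was 4.44-fold lower, from 6575 to 1482. The next higher unnamed probe set, 266364_at, was 2.83-fold higher.

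The gene lists were thinly covered: of 390 members, 46 had a named probe set and 33 were measured. Of these 33 genes, 0 were at least 2-fold higher and 4 were at least 2-fold lower in ros1-1, namely PDF1.2, PDF1.2b, COR15A and COR15B. In the list for cold, drought and abscisic acid response, 2 of 3 measured members were at least 2-fold lower. Its remaining measured member COR47, a dehydrin, had signals of 2923 and 2731, a log2 ratio of -0.10, and LEA4-5 was under the floor on both arrays. The median of the list, -1.03, lay at percentile 0.005 of the random lists, whose medians fell between -0.28 and 0.27 in 95% of draws. That median is the value of COR15B, which lies next to COR15A, while random lists draw genes independently of position. The percentile therefore rests on this pair of neighbours. With an offset in place of the floor, the median was -0.80 and 0 members reached 2-fold. In the jasmonate and ethylene list, both measured members were the defensins named above, and PDF1.1 and THI2.1 were under the floor on both arrays. With the floor at the 25th percentile, the median of this list went from -1.78 to -0.80. The values of PDF1.2 and PDF1.2b did not change there, and the shift came from PDF1.1 and THI2.1, which then counted as measured.

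The measured genes of DNA demethylation, 2 of 14 list members, differed by less than 1.5-fold. DME, a DNA glycosylase related to ROS1, had a signal of 340 in wild type and 246 in ros1-1 in its brightest probe set, a log2 ratio of -0.46, and its other probe sets gave -0.26 and -0.12. With the floor at the 60th percentile, the brightest probe set of DME gave -0.06. The 3′ phosphatase gene ZDP, which acts after the glycosylase, had a log2 ratio of 0.19, the same size as the scatter of probe sets of 1 gene. IDM3 and APE1L were under the floor on both arrays. Of the loci silenced by DNA methylation or imprinting, only QQS had a named probe set, with signals of 29.2 and 36.3 under the floor. In the stomatal lineage list, 4 of 16 members had a named probe set and 2 were measured. FAMA, a regulator of guard cell identity, had a log2 ratio of 0.12 and STOMAGEN, a peptide that promotes stomata, 0.08. SPCH and MUTE were under the floor on both arrays.

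In the other lists, 0 of the measured members were at least 2-fold different. Members with no named probe set, which were most of each list, were not examined. In the root and root hair list, the log2 ratios were 0.51 for EXPA18, 0.33 for EXPA7 and 0.08 for PYK10, and the median of 0.33 lay at percentile 97.6 of random lists. With the floor at the 60th percentile the median was 0.14 and EXPA18 was at 0.20, and with the offset the median was 0.19. In the auxin and cytokinin list, with 4 measured members and a median of 0.22 at percentile 96.7, GH3.3 had a log2 ratio of 0.55 and GH3.5 of -0.42, and ARR15 was under the floor. The median came from the other measured members, which lay under the floor in wild type, so it rests on bounds. With the floor at the 60th percentile, the median of this list was -0.42, which is the value of GH3.5 alone, as the other members fell under that floor. The reference genes UBC21 and SAND had log2 ratios of 0.25 and 0.24, and with TIP41 at 0.10 their median lay at percentile 96.6. The anthocyanin genes UGT75C1 and DFR had log2 ratios of -0.43 and -0.25, and the median of their 3-member list lay at percentile 6.61.

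Lists with 1 or 2 measured members gave single values. The iron deficiency regulators PYE and BHLH101 had log2 ratios of 0.55 and 0.24, and the rapid stress genes WRKY53 and ZAT10 of 0.41 and 0.33. SAG101, a defence regulator, was at 0.43, the clock gene GI at -0.47, and MCCA, of leucine breakdown and the carbon starvation list, at -0.70, or -0.20 with the floor at the 60th percentile. The photosynthesis genes RCA and LHCB4.1 were at 0.21 and -0.15, and the glucosinolate genes UGT74B1 and BCAT4 at -0.22 and -0.12, with AOP3 under the floor on both arrays. The heat shock genes HSP22 and ROF2 and the hypoxia gene HRA1 were under the floor on both arrays.

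Some genes at least 2-fold different were neighbours, as were AT3G16660 and AT3G16670, and COR15A and COR15B. Of 7368 windows of 5 measured genes, 0 held 3 genes at least 2-fold different in 1 direction, and random orders of the same values gave a median of 0 and a highest count of 3. With 27 such genes among 7388, this scan could not tell whether they were grouped. At 1.5-fold there were 2 such windows, and 240 of 1000 random orders gave as many. One of these ran from AT3G16530, a gene outside the naming rule with a log2 ratio of 0.71, to the pair AT3G16660 and AT3G16670. Among the 50 measured genes nearest to the ROS1 locus in gene order, the median log2 ratio was -0.03, and 1 gene, AT2G36885, was at least 2-fold different.

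Control probe sets described the hybridisations. The log2 ratios of 18 probe sets for spiked hybridisation controls had a median of -0.02 and lay between -0.25 and 0.26. The ratio of 3′ to 5′ signal, a sign of RNA integrity and labelling, was 0.207 in wild type and 0.270 in ros1-1 for actin, 1.02 and 0.993 for GAPDH, and 1.18 and 1.45 for ubiquitin. Control probe sets of another design for the same genes gave 1.54 and 1.21 for actin, 0.953 and 0.968 for GAPDH, and 1.84 and 1.74 for ubiquitin, so the direction for each gene differed between designs. A control probe set for 25S ribosomal RNA had a signal of 509 in wild type and 288 in ros1-1.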

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

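The counts of differing probe sets moved with the floor, the treatment of low values and the threshold. Probe sets at least 2-fold higher in ros1-1 numbered 80 with the floor at the 25th percentile, 15 at the 60th and 12 with an offset in place of the floor, and those at least 2-fold lower numbered 99, 19 and 20. A 1.5-fold threshold gave 261 higher and 276 lower and a 3-fold threshold 1 and 10; the neighbour scan at 1.5-fold gave 2 windows. Rescaling moved the counts little: 30 higher and 34 lower after median centring, and 32 and 32 after quantile normalization and after removal of the intensity trend. Plain _at probe sets alone gave 28 and 30. The spread of log2 ratios was 0.31 and 0.23 with the lower and the higher floor. For the 24 genes named as largest on both arrays, all 142 values under the alternatives kept their direction; 72 of 72 stayed at least 2-fold under the scaling alternatives, against 15 of 22 with the floor at the 60th percentile and 13 of 24 with the offset. Both lower that number by construction, since they shrink ratios of dim probe sets. The kept direction was fixed in advance and is no sign of robustness. A floor or an offset cannot reverse a ratio, and rescaling moved ratios by up to 0.15 only. The median of the auxin and cytokinin list was -0.42 with the floor at the 60th percentile, where only GH3.5 was still measured. No alternative could be run for ROS1. Low signal limits these arrays: by steps of 10% of probe sets, the SD of log2 ratios was 0.28 in the dimmest step, whose values lie next to the floor, 0.32 in the next and 0.21 in the brightest.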

Other observations

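The families described here were chosen after the annotation had been seen, the chloroplast groups after the values. Among defensins and defensin-like peptides, a family edited after its values were seen, 6 of 7 measured members had a lower signal in the ros1-1 array, and the family median of -0.34 lay at percentile 0.03 of random lists. Without PDF1.2 and PDF1.2b, 4 of 5 members were lower, and the median of -0.20 lay at percentile 2.52, at the edge of the range that held 95% of random lists. LCR67, also called PDF1.1, had a deposited signal of 68.1 in wild type and 131.5 in ros1-1, just under the floor, and was not counted. The list of cytochromes P450, enzymes of oxidative metabolism, took 23 genes by symbol and leaves out P450 genes with no named probe set. Its median was -0.28 at percentile 0.385, with 8 of 11 measured members lower. Of these 11, 10 were CYP71B genes, so the list describes mainly that subfamily. Of the 10 CYP71B genes, 7 were lower, with a median of -0.24. The stretch of CYP71B locus codes from AT3G26150 to AT3G26330, chosen after the values were seen, held 6 lower genes of 7, with a median of -0.38, and the others were CYP71B28 at 0.28, CYP71B6 at 0.03 and CYP71B5 at -0.12. The genes of this stretch are similar tandem copies, so their probe sets may share signal, and the family median was -0.12 with the floor at the 60th percentile. UDP-glycosyltransferases had 15 of 23 members lower, with a median of -0.13 at percentile 2.04, and beta-glucosidases had 7 of 11 higher, with a median of 0.15 at percentile 97.7, or 0.04 with the floor at the 25th percentile. In the families named so far 0 members other than the defensins PDF1.2 and PDF1.2b reached 2-fold, and 6 of the 24 lists placed among random lists lay outside the range that held 95% of these, against 1.2 for unrelated lists of unchanged genes. In the simulated comparison of ros1-1 with wild type over 22746 probe sets, 3 of 100 unchanged lists did. Both numbers hold for lists of unrelated genes drawn at random, whereas these families hold related genes that can move together. The defensin family was also edited after its values were seen. Neither number is therefore a fair measure for these lists, and no excess is shown. Of 989 pseudogene loci with a probe set, 26 were measured, with a median of 0.08 at percentile 92.1, or -0.06 with the floor at the 60th percentile, and 0 members at 2-fold.

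Of 68 measured chloroplast-encoded genes, 34 were higher and 34 lower in ros1-1, and their median of 0.00 lay at percentile 18.6. The groups and genes that follow were chosen after their values were seen, and no difference between groups was tested. How well 3′ expression arrays measure chloroplast and mitochondrial transcripts was not tested either. All 4 measured subunits of the plastid-encoded RNA polymerase were lower in ros1-1, with rpoB at -0.83, and 9 of 9 ndh genes, for the NAD(P)H dehydrogenase-like complex, were higher, with a median of 0.14. The ndh ratios ran from 0.02 to 0.26, against a scatter of 0.19 between probe sets of 1 gene. Most genes of both groups have neighbouring locus codes, so these are not counts of independent genes. The rpo genes were lower in 4 of 4 under each scaling alternative, while the ndh genes were higher in 8 of 9 after quantile normalization and 7 of 9 after removal of the intensity trend. The pet genes, for the cytochrome b6f complex, were lower in 5 of 6, with a median of -0.21. Medians were 0.13 for psa, 0.02 for atp, -0.05 for rps and -0.06 for rpl genes, with members in both directions. After quantile normalization and trend removal, they were 0.06 and 0.08 for psa, -0.02 and -0.03 for atp, and -0.11 and -0.11 for rpl genes. Among photosystem II genes 11 of 15 were lower, with psbD at -0.74 as the lowest and psbN at 0.56 as the highest, and ycf3, a photosystem I assembly factor, was at -0.87. The 5 measured mitochondrial genes were lower, with a median of -0.08 at percentile 33.4. The remaining families had medians between percentiles 9.64 and 90.3, and 0 of their members reached 2-fold. The SWEET family among them was built from symbols and leaves out SAG29, or SWEET15, which was 2.33-fold higher.

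The defensins PDF1.2 and PDF1.2b were both lower in ros1-1. A difference in scaling or an intensity trend is argued against only as far as the 3 scaling alternatives capture it. These moved other probe sets by up to 0.15, far less than the PDF1.2 ratio, which was at most -2.11 under them. The genotype and any other difference between the RNA samples, such as a jasmonate or ethylene response of the seedlings in 1 sample, cannot be told apart with 1 array per genotype. Lower PDF1.2 through loss of ROS1 may therefore be stated only as a hypothesis.

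COR15A and COR15B are adjacent genes and were both lower. Scaling is argued against here within the same limit, as the ratio closer to 0 was -1.005 over the same alternatives. A lower cold and drought response across the list stays open: its only other measured member, COR47, was at -0.10, and 1 gene with a scatter of 0.19 does not decide it. A growth difference between the seedling samples and an effect of ros1-1 also remain open and were not tested.

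AT3G16660 and AT3G16670 were the named neighbours with higher signal in ros1-1. A change of the whole region is argued against, since the 10 nearest measured genes had a median log2 ratio of -0.026, from -0.44 to 0.71. The closest of these, AT3G16630 and AT3G16690, were at 0.01 and -0.06, and a change confined to the stretch between them is not addressed. Scaling or an intensity trend is argued against within the limit given for PDF1.2, since the lower of the pair's ratios was 1.48 over the scaling alternatives. A local effect on the pair of the impaired demethylase is a possible explanation, and so is a difference between the plants, which these arrays do not separate. Shared signal between the related copies was not tested.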
